A study of Oryza sativa Japonica Group with 6 samples.

How the data were processed

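The series holds 6 polyA RNA libraries from leaves of 14-day-old rice seedlings (Oryza sativa, Japonica group), sequenced on an Illumina instrument. Per the labels, 3 libraries are wild type (WT) and 3 come from OsWRKY65-2, a line that overexpresses the transcription factor OsWRKY65. Nothing in the labels says that the replicates came from separate plants or days, so p-values measure the spread between these libraries, which may in part be technical.

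The deposited table gives, per the file headers, a read count, an FPKM and a TPM for each of 37863 genes in each library, with RAP-DB gene identifiers, a text annotation and an older locus name. Per the submitters' processing notes, bcl2fastq 2.20.0, Trimmomatic, HISAT2 2.1.0 and StringTie 2.1.3b were used with the genome build IRGSP-1.0. The order of steps, the counting options, the strand setting and the annotation release are not given in the sources used here. The deposited read counts are estimated counts, already whole: among 5477 genes with 1 transcript and a count above 500 in the first pair of WT libraries, the ratio of FPKM to count was constant between those libraries to within a spread of 0.234% (1st to 99th percentile). The FPKM values deposited by the authors are counts scaled to transcript length and library size, and were used only in that check. The TPM values deposited by the authors sum to 1000000 in each library and were used in 2 alternatives. With no strand information, reads of overlapping and antisense genes cannot be told apart, and near-identical copies, such as those on the duplicated ends of chromosomes 11 and 12, can share reads.

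The 3 table columns named for OsWRKY65-2 carry that line's name and replicate number. The other 3 columns carry a prefix that the labels do not explain, and were taken as WT because they are the only columns left for the 3 WT samples. The direction of every comparison rests on this reading. The gene to report as OsWRKY65 was fixed before the data were examined as the one annotated WRKY65 or, failing that, Os12g0116700 if its annotation named a WRKY protein. No gene is annotated WRKY65, and Os12g0116700 is annotated as WRKY transcription factor 64. Os12g0116800, whose older locus name is, from general knowledge, that of OsWRKY65, was therefore used in its place. This change was made after the counts of both genes had been seen, and both are reported. No coordinates are given in the table, and the gene reference at hand belongs to another assembly without RAP-DB identifiers, so chromosomes are those encoded in the identifiers and no positions are printed.

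Total counts ranged from 20585288 to 29720852 per library. The floor used for a count of 0 was 3 counts, which correspond to between 0.0917 and 0.160 CPM (counts scaled to a library of 1000000) in single libraries. Floors cover counting error only, and every library held few genes with a count of 1 (63 to 247), so that the table may leave out low values and a count of 0 may hide more than the floor. CPM were computed with TMM factors.

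The main test, fixed before the data were examined, was edgeR 4.0.16 (R 4.3.3) with the robust quasi-likelihood test, TMM factors, filterByExpr with a minimum count of 10 and genotype as the sole term. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and fold changes use a prior count of 2. The SE given with an edgeR log2 fold change is its absolute value divided by the square root of the test's F statistic. For genes at 0 counts in a genotype, both depend on the prior count. Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, over the 48 lists with at least 5 tested members out of 50 fixed beforehand. The lists were text patterns on the annotation plus 53 remembered identifiers whose annotation matched, while 7 others were dropped. After the annotations were read, the patterns of 5 lists were corrected for accidental matches, such as germination for germin, and the lists as first written were run as an added alternative. Alternatives chosen before the data were examined were other normalization factors, other filters, DESeq2 1.42.0, limma-voom, limma-trend on log2(TPM + 1) and log2(TPM + 0.1), a replicate block, each library left out in turn, and for lists an estimated correlation and fry. Chosen after seeing the data were sample quality weights and combinations of other settings with the omission of OsWRKY65-2 replicate 3.

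Genes were to be named by rule: OsWRKY65, then the 8 largest changes each way and the 6 smallest adjusted p among called genes with separated replicates, at least 5 CPM and an informative annotation, up to 4 called members of each list that passed, and the WRKY neighbours on chromosomes 11 and 12 at 1 CPM or more. The main test called no gene. The rule was therefore applied to the planned omission of OsWRKY65-2 replicate 3, and the 8 smallest unadjusted p and 1 or 2 members of called lists with the smallest p were added, of which those in the text are a part. All genes other than the WRKY neighbours were thus chosen after the data had been seen, the gene taken as OsWRKY65 included.

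The pipeline was tested on simulated counts with 200 changed genes. At the spread of all 6 libraries (23764 genes), edgeR called 0% of the genes changed 2-fold, 6% at 4-fold, 36% at 8-fold and 68% at 16-fold, with 4 false calls, and DESeq2 called 61% of the 200 with 186 false calls. At the spread without OsWRKY65-2 replicate 3 (24671 genes), edgeR called 10%, 84%, 94% and 96%, with 16 false calls, and DESeq2 called 78% of the 200 with 85 false calls.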

Results

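Leaf transcript levels were measured in 3 WT and 3 OsWRKY65-2 libraries of 14-day-old rice seedlings, to compare the profiles of a line overexpressing the WRKY transcription factor OsWRKY65 with those of wild type. Total counts were 22618996, 29720852 and 24838297 in WT replicates 1 to 3, and 20894242, 28361580 and 20585288 in OsWRKY65-2 replicates 1 to 3. Between 24091 and 27129 genes had a count in 5 of the libraries, against 20893 in OsWRKY65-2 replicate 3. That library stood apart from all others. Its log2 CPM correlated with those of the other libraries across genes at r = 0.603 to 0.695. The highest value was with OsWRKY65-2 replicate 1, against 0.629 or less with the rest. Pairs without OsWRKY65-2 replicate 3 reached 0.856 to 0.926 (genes are not independent replicates). The first principal component, 69.6% of the variance, separated OsWRKY65-2 replicate 3 from the rest. Of those, OsWRKY65-2 replicate 1 lay nearest to it on that component.

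**Figure D1:**
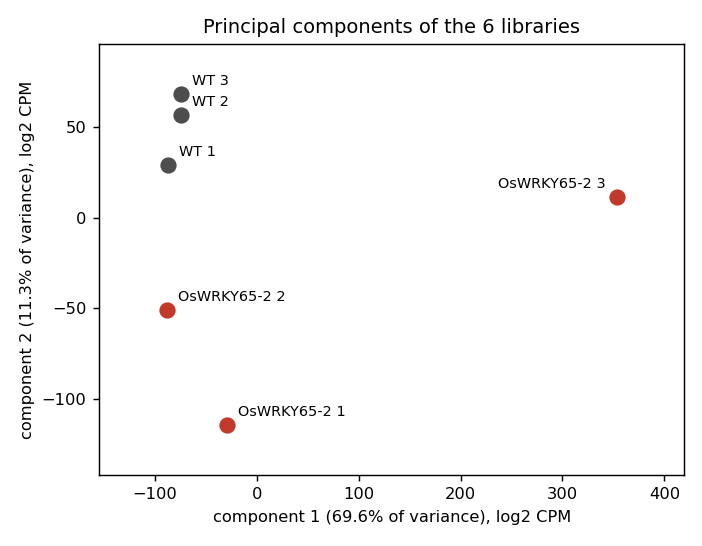
Principal components of log2 CPM for the 6 libraries (grey, WT; red, OsWRKY65-2), with each axis in log2 CPM units and its share of variance. OsWRKY65-2 replicate 3 lies alone at 353.4 on component 1, while the other libraries lie between -88.4 and -29.4.

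The gene taken as OsWRKY65, Os12g0116800 on chromosome 12, was at 4.16, 0 and 0 CPM in the WT libraries and at 69.5, 42.3 and 1039.6 CPM in the OsWRKY65-2 libraries, above WT in 3 of 3. Means were 1.39 ± 2.40 CPM in WT and 384 ± 568 CPM in OsWRKY65-2 (SD, n = 3 each), a log2 fold change of 8.04 ± 2.62 (SE) with an adjusted p of 0.763 in edgeR's quasi-likelihood test. An exact two-sided permutation test of CPM gave p = 0.10, the smallest that 3 against 3 libraries allow. The difference therefore did not pass the threshold on the adjusted p, and the permutation test could not have gone under 0.05. Unadjusted, the edgeR p of this single gene was 0.0211, and 0.00978 without OsWRKY65-2 replicate 3. The gene was, however, chosen after its counts had been seen. OsWRKY65-2 replicate 3 carried 18.6 times the mean of replicates 1 and 2. Without it the log2 fold change was 5.29 ± 1.49 (adjusted p = 0.304, edgeR), and without WT replicate 1, the sole WT library with counts, 12.22 ± 2.67 (adjusted p = 0.999, edgeR). The neighbour Os12g0116700, annotated as WRKY transcription factor 64 and the gene the rule fixed beforehand would have taken, had a log2 fold change of 1.55 ± 2.45 (adjusted p = 0.919, edgeR) and counts of 0 in WT replicates 2 and 3 and in OsWRKY65-2 replicate 3. Leaving out 1 library moved this value to between 0.97 and 5.98, the highest without WT replicate 1 (adjusted p of 0.725 or more, edgeR). Of the other WRKY genes in the duplicated ends of chromosomes 11 and 12, Os11g0117600, annotated as a transcriptional repressor in abscisic acid responses, was at 3.41 ± 2.08 CPM in WT and 15 ± 10.6 CPM in OsWRKY65-2 (n = 3 each), but OsWRKY65-2 replicate 3, at 3.10 CPM, lay below WT replicate 1, at 5.68 CPM. Os12g0116400 was at 1.68 ± 0.378 and 6.36 ± 5.48 CPM, with every OsWRKY65-2 library above WT, and neither passed the test (adjusted p = 0.763 for both, edgeR). OsWRKY65-2 replicate 3, at 12.7 CPM, carried the latter mean, and the log2 fold change of Os12g0116400 went from 1.87 to 0.90 without it. That of Os11g0117600 went the other way without this library, from 2.11 to 2.60 ± 0.49 (SE, adjusted p = 0.151, edgeR). Like Os11g0117600, the genes Os11g0116900, Os11g0117400 and Os11g0117500 overlapped between genotypes, at log2 fold changes of -0.03, 0.49 and 0.93. Copies in these chromosome ends can share reads, so the split among them is uncertain.

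Over all 6 libraries, edgeR called 0 of 23769 genes higher and 0 lower in OsWRKY65-2, and so also 0 at 2-fold or more. At an unadjusted p under 0.05 there were 1547 genes. DESeq2 called 181 higher and 105 lower, limma-voom 0 and 0, and limma-trend on log2(TPM + 1) 2 higher and 0 lower. The OsWRKY65-2 libraries all lay above WT for 1701 genes and all below for 2504, together 17.7% of tested genes. Apart from ties, the average over all splits of the libraries into groups of 3 is 10%. The share in other splits was not computed and genes vary together, so the excess is not a test of genotype. Without OsWRKY65-2 replicate 3, edgeR called 13 of 24677 genes higher and 6 lower, and each of the other 5 omissions left 0.

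Without replicate 3, 6 annotated genes were called higher in OsWRKY65-2. Os02g0677300, a CBF/DREB1 transcription factor of cold tolerance, rose from 0.418 ± 0.0445 CPM in WT (n = 3) to 13.6 ± 8.26 CPM (n = 2), a log2 fold change of 4.79 ± 0.49 (SE, adjusted p = 0.0311, edgeR). Os11g0454300, a group 2 late embryogenesis abundant protein of salt tolerance, rose from 0.406 ± 0.394 to 25.1 ± 1.12 CPM, and Os09g0541000, a plasma membrane aquaporin, from 11.5 ± 4.36 to 85.8 ± 6.85 CPM (adjusted p = 0.0317 for both, edgeR). Os04g0249600, annotated as an arsenate reductase of the rhodanese family, rose 7.37-fold, from 6.71 ± 1.40 to 49.5 ± 10.8 CPM (adjusted p = 0.0220, edgeR). The inositol monophosphatase Os07g0558300 rose 5.57-fold (adjusted p = 0.0310, edgeR). The cytochrome P450 gene Os03g0371000 had 0 counts in every WT library and 13.6 ± 1.5 CPM in OsWRKY65-2 (adjusted p = 0.0220, edgeR). In replicate 3, which did not enter this test, all 6 of these genes also lay above every WT library, at 14.3, 305.6, 118.2, 67.5, 23.3 and 164.3 CPM in the order named.

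Without replicate 3, 4 annotated genes were called lower. Os04g0340300, annotated as an (S)-limonene synthase, which makes a monoterpene, fell from 82.1 ± 29.1 CPM in WT to 2.17 ± 1.58 CPM, a log2 fold change of -5.16 ± 0.56 (SE, adjusted p = 0.0317, edgeR). Os03g0291500, an asparagine synthetase, fell from 661 ± 192 to 102.0 ± 3.17 CPM, and the peroxidase Os03g0339300 from 48.5 ± 5.79 to 10.9 ± 1.99 CPM (adjusted p = 0.0317 for both, edgeR). Os01g0106400, an isoflavone reductase-like protein linked to reactive oxygen homeostasis, fell from 46.4 ± 13.0 to 3.63 ± 1.87 CPM (adjusted p = 0.0410, edgeR). In replicate 3 these genes were at 0, 231.5, 0 and 0.374 CPM in the order named, all below WT. Low values there are weak evidence, however. In that library 2444 genes with a median count above 50 elsewhere were at 0, against 28 to 198 in each other library. The other 9 of the 19 calls, 7 higher and 2 lower, have no informative annotation. Omitting that library was planned, but it was taken up as a source of named genes only after the library was seen to stand apart, and the OsWRKY65-2 group then holds 2 libraries. In the simulation at the spread without it, edgeR called 71% of the 200 changed genes and made 16 false calls. With all 6 libraries none of the 10 annotated genes passed edgeR's test (adjusted p from 0.337 to 0.770). On the 5 libraries without replicate 3, limma-voom kept Os09g0541000, Os04g0249600, Os07g0558300, Os03g0291500 and Os03g0339300, while Os02g0677300, Os11g0454300, Os03g0371000, Os04g0340300 and Os01g0106400 fell short (adjusted p = 0.208, 0.0831, 0.109, 0.0738 and 0.0633). With the replicate number as a block in edgeR, none of the 10 passed on these libraries (adjusted p from 0.0653 to 0.169).

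**Figure D2:**
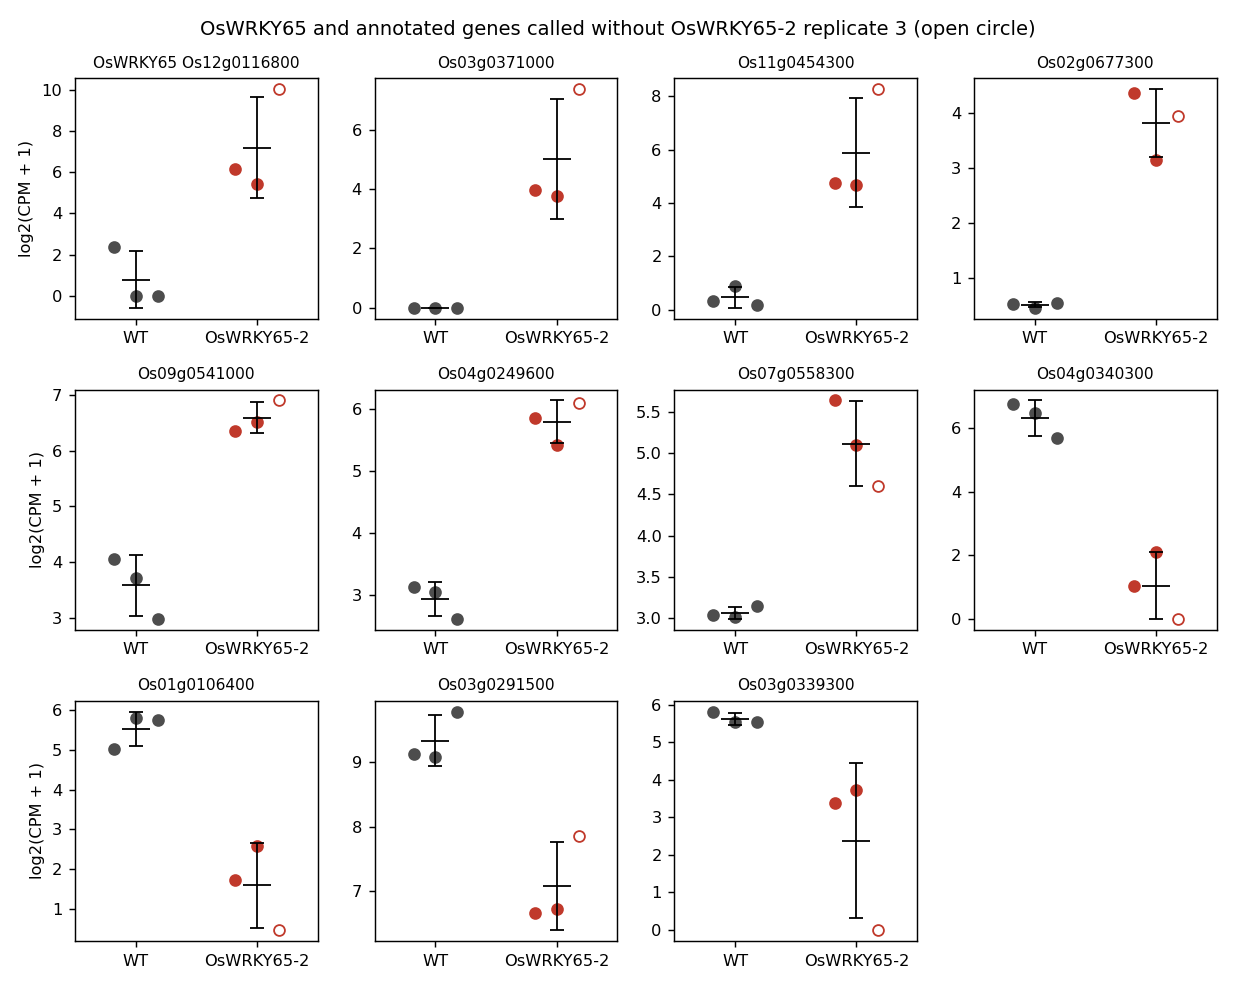
Expression of OsWRKY65 and the 10 annotated genes called without OsWRKY65-2 replicate 3, as log2(CPM + 1) per library (grey, WT; red, OsWRKY65-2; open circle, OsWRKY65-2 replicate 3), with the mean and SD of all 3 libraries of each genotype; each panel has its own vertical range. Every OsWRKY65-2 library lies on one side of every WT library in each panel, and OsWRKY65 spans 42.3 to 1039.6 CPM within its line.

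Light-harvesting and photosystem proteins had the smallest camera p of the gene lists at the preset correlation, although other lists had larger median changes, such as phytoalexin synthesis (1.94, not called). Of 57 tested members, 42 had a positive fold change, with a median log2 fold change of 0.60 (camera adjusted p = 2.65e-07, but adjusted p = 0.577 with an estimated correlation). In 21 members every OsWRKY65-2 library lay above every WT library. Both directions together average 10% over all splits of the libraries, but members vary together and single splits can differ from that average. No member passed the test over all genes, and 0 passed adjusted over the list alone. Plastocyanin, the electron carrier Os06g0101600, was at 615 ± 166 CPM in WT and 1370 ± 156 CPM in OsWRKY65-2, and the CP29 antenna gene Os07g0558400 at 1200 ± 388 and 2307 ± 276 CPM (n = 3 each, adjusted p = 0.763 for both, edgeR). Per-library medians relative to the WT mean were -0.17, -0.26 and 0.44 in WT and 0.64, 0.44 and 0.69 in OsWRKY65-2, so WT replicate 3 lay within reach of the line. The morning clock gene LHY (Os08g0157600), on the same scale, was at -0.35, -0.37 and 0.72 in WT and 1.42, -0.35 and 1.45 in OsWRKY65-2, so it went with this list except in OsWRKY65-2 replicate 2, and a part for time of day was not tested. The list also ranked higher without OsWRKY65-2 replicate 3 (median 0.55, camera adjusted p = 2.18e-06, but adjusted p = 0.701 with an estimated correlation).

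A further 6 lists ranked higher with the preset correlation, and 0 of their members passed the test over all genes. Adjusted over the list alone, 0 members passed for redox enzymes and 0 for heat shock proteins. Of 130 redox enzymes 80 had a positive fold change (median 0.21, camera adjusted p = 0.0261, and adjusted p = 0.408 with an estimated correlation). The copper/zinc superoxide dismutase Os03g0219200 was at 36.2 ± 2.73 CPM in WT and 89.2 ± 16.8 CPM in OsWRKY65-2, and its relative Os07g0665200, annotated as a target of miR398b, at 32.5 ± 3.32 and 92.4 ± 19.3 CPM (n = 3 each). Of 146 heat shock proteins 96 were positive (median 0.22, camera adjusted p = 0.0145, and adjusted p = 0.385 with an estimated correlation), among them Os03g0821100, an HSP70 cognate, at 121 ± 26.9 and 242 ± 48.3 CPM. Of 66 WRKY genes, OsWRKY65 included, 46 were positive (median 0.48, camera adjusted p = 0.0145, and adjusted p = 0.577 with an estimated correlation), and 1 passed adjusted over the list alone. Os09g0417600, annotated as a splicing variant of OsWRKY76, was at 5.86 ± 1.60 CPM in WT and 24.5 ± 2.30 CPM in OsWRKY65-2.

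The WRKY list and the other 3 lists that ranked higher took their level mostly from OsWRKY65-2 replicate 3. Medians in that library relative to the WT mean were 0.98 for WRKY genes, against 0.19 and 0.04 in replicates 1 and 2. They were 1.33 for glutathione S-transferases, 1.10 for UDP-glucosyltransferases and 0.63 for abscisic acid and dehydration genes, against -0.06 to 0.58 in replicates 1 and 2. In these last 3 lists, in the order named, positive fold changes were found for 28 of 38, 55 of 84 and 37 of 60 members (camera adjusted p = 0.0256, 0.0444 and 0.0261, and adjusted p = 0.634, 0.577 and 0.577 with an estimated correlation), and 0 members of each passed adjusted over the list alone. Os05g0542500, a late embryogenesis abundant protein, had 0 counts in WT and 26.2, 4.64 and 451.4 CPM in the line. Without that library none of these 3 lists passed (camera adjusted p = 0.894, 0.894 and 0.564), nor did the WRKY, heat shock and redox lists (0.564, 0.221 and 0.116), and camera placed glutathione S-transferases lower although their median stayed positive (0.11).

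In all, 3 lists ranked lower over the 6 libraries, with 0 members called and 0 adjusted over the list alone. In the cell wall list 12 of 60 members were positive (median -0.70, camera adjusted p = 0.00348, and adjusted p = 0.756 with an estimated correlation). Plastid ribosomal proteins had 12 of 53 positive (median -0.40, camera adjusted p = 0.00311, and adjusted p = 0.756 with an estimated correlation). Both fell short without OsWRKY65-2 replicate 3 (camera adjusted p = 0.0567 and 0.222). In that library their medians were -3.07 and -1.43 relative to the WT mean. Class III peroxidases and germin-like proteins had 35 of 99 positive, with 23 members below WT in every OsWRKY65-2 library (median -0.51, camera adjusted p = 0.0118, and adjusted p = 0.577 with an estimated correlation). This list also ranked lower without replicate 3 (median -0.50, camera adjusted p = 2.90e-05, and adjusted p = 0.701 with an estimated correlation), with 1 member called. It passed over all 6 libraries only with its text pattern as corrected after the annotations were read (camera adjusted p = 0.0997 as first written).

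A further 5 lists passed only in the camera test without OsWRKY65-2 replicate 3; whether they differ between the 2 fits was not tested. Cell division genes and histones (median 0.45, adjusted p = 5.07e-10), cytosolic ribosomal proteins (0.30, adjusted p = 3.14e-06) and shoot meristem genes (0.85, adjusted p = 0.00834) ranked higher. Pathogenesis-related proteins (-0.67, adjusted p = 0.00478) and terpene synthases (-0.78, adjusted p = 0.0372) ranked lower. With an estimated correlation the adjusted p of these lists lay between 0.701 and 0.754. Medians of single libraries relative to the WT mean overlapped between genotypes for all of these lists but cell division. For the meristem list they were 0.23, 1.28 and -1.46 in WT and 0.92 and 2.00 in OsWRKY65-2 replicates 1 and 2, so WT replicate 2 lay within the line and WT replicate 3 below the other 4 of these libraries. Terpene synthases were at 0.46, -0.42 and -0.34 in WT and at 1.39 and -0.37 in these replicates. Over all 6 libraries, camera placed cell division genes and pathogenesis-related proteins lower without a call, while their medians were 0.13 and 0.18. In replicate 3 itself the cell division median was -2.82 relative to WT, against 0.27 and 0.63 in replicates 1 and 2.

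**Figure D3:**
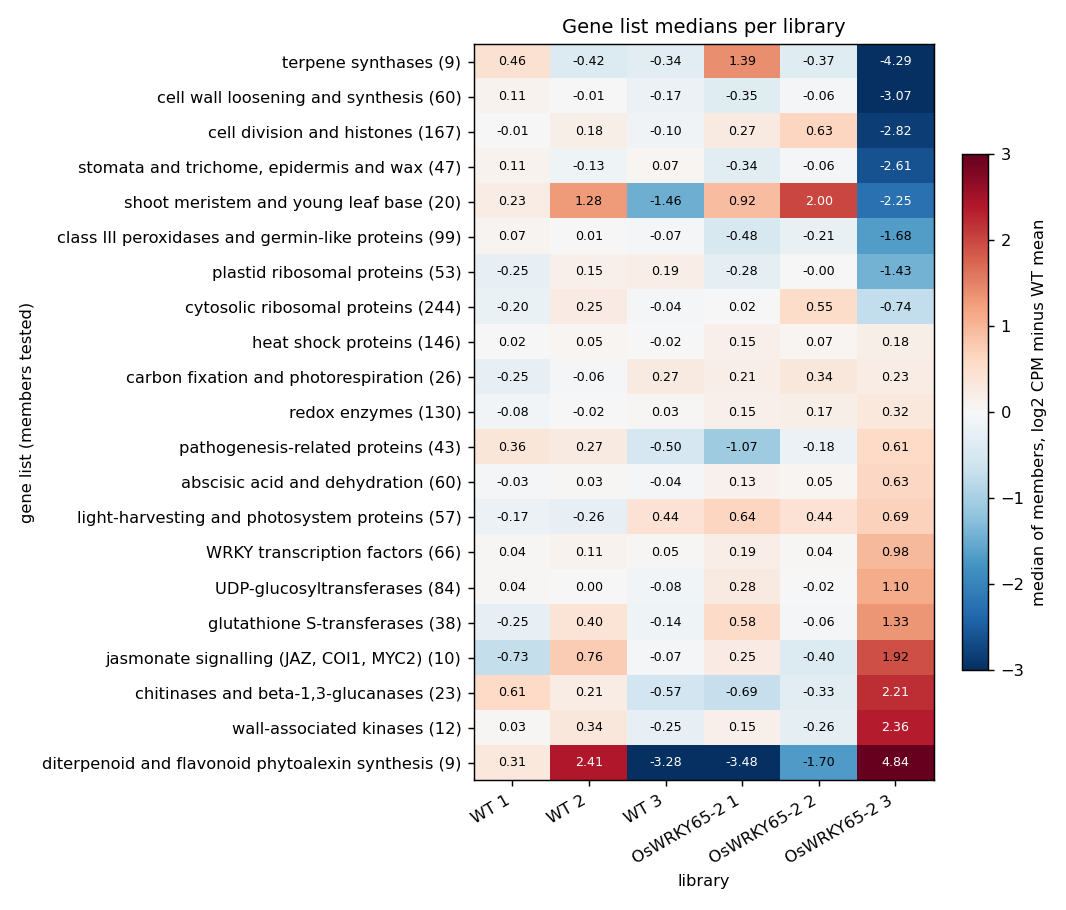
Median log2 CPM of list members relative to the WT mean of each gene, per library, for lists that passed camera in either fit and 6 lists shown for comparison (number of tested members in brackets; colour scale limited to -3 and 3). OsWRKY65-2 replicate 3 holds both extremes, from -4.29 for terpene synthases to 4.84 for phytoalexin synthesis.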

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

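The tests with sample weights, with 2 settings changed together and with the lists as first written were chosen after seeing the data. OsWRKY65 stayed higher in all settings, past the threshold in none, at log2 fold changes from 6.60 to 10.48 with all libraries and from 5.28 to 12.22 with 1 left out (no value with the stricter filter and without OsWRKY65-2 replicate 3, which removed it) (adjusted p from 0.184 to 0.999, and NA in DESeq2). Genes called higher and lower were 0 and 0 with other normalization factors, the stricter filter, limma-voom or the replicate block. They were 2 and 0 with no filter and with limma-trend at either pseudocount. DESeq2 gave 181 and 105 (175 and 96 at 2-fold), and limma-voom with sample weights 6 and 1. With 1 library left out the counts ranged from 0 to 13 higher and from 0 to 6 lower (the same at 2-fold), and all calls came from omitting OsWRKY65-2 replicate 3. Without that library, DESeq2 gave 274 and 435 (236 and 336 at 2-fold), limma-voom 5 and 3, DESeq2 size factors 13 and 6, the stricter filter 5 and 5, and the replicate block 7 and 1. DESeq2 with all libraries shared 16 of the 19 genes edgeR called without replicate 3, limma-voom 6 of its 8 and the block 2 of its 8. In the simulation at the spread of all 6 libraries, DESeq2 made 186 false calls and edgeR 4. At the spread without OsWRKY65-2 replicate 3 they made 85 and 16. The simulation gave each gene the same dispersion in all libraries, so these numbers may not carry over to the data. The cause of these differences was not tested.

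Lists called higher and lower, 7 and 3, became 0 and 0 with an estimated correlation or fry, and 0 and 0 with an estimated correlation without replicate 3. Leaving out 1 library gave 4 to 11 higher and 3 to 5 lower. The replicate block gave 5 and 3, and the lists as first written 7 and 2. Whether the replicate numbers pair the samples was not settled. Deviations of same-numbered libraries from their genotype means correlated across genes at 0.0498, -0.0581 and -0.00648. Those of differently numbered libraries correlated at -0.0883 to 0.0928. The OsWRKY65-2 mean includes replicate 3, which stood apart, so a pairing could stay hidden.

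Directions turned as follows. Leaving out 1 library moved the log2 fold change of Os11g0116900 from -0.73 to 0.36, Os11g0117400 from -0.0696 to 2.31 and Os11g0117500 from -0.55 to 4.30. Upper quartile factors gave Os11g0116900 0.0019. Without OsWRKY65-2 replicate 3, Os11g0117400 was at -0.077 (DESeq2), -0.078 (its size factors) and -0.80 (block), and Os11g0117500 at -0.63, -0.54 and -0.48. Sample weights gave Os11g0117500 -1.58. List medians with 1 library left out ranged from -0.43 to 0.45 (cell division), -0.33 to 0.30 (cytosolic ribosome), 0.11 to 1.08 (glutathione S-transferases), -0.67 to 0.45 (pathogenesis-related) and -0.29 to 0.95 (meristem). Cytosolic ribosomal proteins turned with fry (median 0.044) and with total counts (-0.12). With an estimated correlation and without replicate 3, glutathione S-transferases (0.11) and cell division (0.45) ranked opposite to the fit of all libraries. The median of all genes shifted to -0.19 with total counts and to -0.29 and -0.34 on the TPM scale. Depth was 20585288 counts or more per library.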

Other observations

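All tests in this part were chosen after the result was seen, except the counts of genes and lists called in other splits. Relative to the WT mean, OsWRKY65-2 replicate 3 held high levels of transcripts of some defence lists, but not of others. Phytoalexin synthesis genes had a median 4.84 above the WT mean on the log2 scale in that library, against -3.48 and -1.70 in replicates 1 and 2, and 0.31, 2.41 and -3.28 in WT. Os06g0569500, an ent-kaurene oxidase of diterpenoid phytoalexin synthesis, was at 449 CPM there, at 0 in replicates 1 and 2 and at 41.8 CPM in WT replicate 2. The defence protein gene Os12g0555500 (PBZ1) was at 446 CPM and the Clp protease ATPase and chaperone gene Os02g0526400 at 3253 CPM, against 0.629 to 76.9 and 29.4 to 187 CPM in the other libraries. Chitinases and glucanases (2.21), wall-associated kinases (2.36) and jasmonate signalling genes (1.92) were also above the WT mean. NB-ARC proteins (-0.01), proteinase inhibitors and thionins (-0.01) and leucine-rich repeat receptor kinases (0.06) lay near it, and class III peroxidases and germin-like proteins (-1.68) below it. Lists near the WT mean could still rank high against random lists of matched expression. By median log2 CPM in replicate 3 minus the mean of replicates 1 and 2, NB-ARC proteins lay at percentile 99.6. Proteinase inhibitors and thionins lay at 99.47 and leucine-rich repeat receptor kinases at 87.8. In the opposite direction, 40 genes with a mean of 100 CPM or more in the other 5 libraries had 0 counts, against 1 to 4 such genes in any other library. They included the lipid transfer protein gene Os12g0114800 and Os12g0590500, a kinesin.

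The morning clock gene LHY (Os08g0157600) was at 119, 117 and 250 CPM in WT and at 405, 119 and 414 CPM in OsWRKY65-2, so that libraries of both genotypes differed in this time-of-day transcript. Among genes without an informative annotation, chosen after their values were seen, Os03g0115800 had 0 counts in WT and 118.7, 79.0 and 126.2 CPM in OsWRKY65-2, and Os03g0299700 had 0 and 57.8, 58.6 and 48.6 CPM. Os05g0542150 showed the reverse, at 10.2, 10.2 and 11 CPM in WT and 0 in OsWRKY65-2.

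The first pattern weighed is the distance of OsWRKY65-2 replicate 3 from the rest. Random loss of transcripts from a library of low complexity is argued against as the whole account, since 10 of 48 lists had a share of members at 0 outside the central 99% of matched random lists (33.5% of cell division genes, where matched lists gave 12.2%). Less growing tissue in the sample cannot be told apart from arrested growth in the same tissue or other accounts. Lists were also ranked by the median, over members, of log2 CPM in replicate 3 minus the mean of replicates 1 and 2. On this measure the 4 lists taken for growing tissue lay below the 0.5 percentile of matched lists, while light harvesting lay at 99.8. Those 4 were cell division, meristem, cell wall, and epidermis and wax. They were picked after their levels in this library had been seen and so restate the pattern. Ribosomal proteins of the cytosol and plastid, auxin response genes and the peroxidase list lay below the 0.5 percentile as well. Light harvesting was not alone at a high percentile. NAC transcription factors, UDP-glucosyltransferases, redox enzymes and heat shock proteins lay at 100, 100, 99.94 and 99.84. A higher level of OsWRKY65, 18.6 times that of replicates 1 and 2, cannot be told apart from any other property of this single library.

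The second pattern is the range of OsWRKY65 within its line. Carry-over of reads from replicate 3 into replicates 1 and 2 would give every abundant gene of replicate 3 at least the shares seen for OsWRKY65, 6.69% and 4.07%. Of 1931 other genes at 100 CPM or more there, 38 lay more than 3-fold below these shares in both libraries, and the laccase gene Os12g0257600, at 746 CPM, was at 0 in both. This test replaced a first form on 32 genes high in replicate 3 and near 0 in WT, which had not decided: their median shares were 5.01% and 0.937%. That replicate 3 is a WT library under a wrong label is argued against. Of 8 other genes absent from WT and high in replicates 1 and 2, 7 had counts in replicate 3. The level of OsWRKY65 itself, 1039.6 CPM there against 4.16, 0 and 0 CPM in WT, was known before this test and left out of it. Differences between plants of the line in transgene level stay open and were not tested.

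A further pattern is 39 genes present in every library of 1 genotype and at 0 in the other, 24 in OsWRKY65-2 and 15 in WT. Chromosome segments that differ between seed stocks may contribute: 8 of these genes had another within 20 expressed genes in identifier order, p = 0.0110 in a permutation test of 10000 matched random draws. Genes of both genotypes were pooled in this count. Most of the close identifiers were present in opposite genotypes. These were Os02g0162200 (WT) and Os02g0162600 (OsWRKY65-2), Os05g0542150 (WT) and Os05g0542500 (OsWRKY65-2), and Os10g0476200 (WT) and Os10g0474700 (OsWRKY65-2). Only Os04g0397800 and Os04g0397901 were present in the same genotype (OsWRKY65-2). Windows of 10, 40 and 100 genes gave p = 0.0010, 0.0049 and 0.217 in the same permutation test. Segments cannot be told apart from other accounts, since 1 of 9 other splits of the libraries also gave clustered genes and another split gave 55 such genes.

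The 6 libraries allow 10 splits into groups of 3, too few for a share under 0.05. For calls of single genes the real split gave 0 and the highest other split 0, so this count cannot set the real split apart. At an unadjusted p under 0.05, a count taken up after it was seen, the real split gave 1547 genes and the highest other split 1357. For gene lists the real split gave 10 and the highest other split 22, and 10 of 10 splits gave at least as many lists, so camera with the preset correlation called lists in groupings that mix the genotypes.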
